A study of Drosophila melanogaster with 18 samples.

How the data were processed

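Poly-A RNA of Drosophila melanogaster ovaries, with the tissue given as stages 1 to 7, was sequenced in 18 libraries. The flies came from 2 inbred lines, HP (high plasticity) and LP (low plasticity), named for how readily they enter reproductive diapause, an arrest of egg production. Each line had 3 groups of 3 libraries, described in the labels as biological replicates. Diapause and reproductive ovaries came from flies kept at 12 °C, and age-control ovaries came from 28-day-old flies kept at 25 °C. The age of the flies kept at 12 °C was not given in the sources used here. RNA was extracted with a mirVana kit, and libraries were made with the NEBNext Ultra II Directional kit, per the labels' protocols.

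The submitters' processing notes name Trimmomatic, STAR, featureCounts and DESeq2, without their roles. Their versions, their settings and the genome build were not given in the sources used here. The deposited table held raw read counts per gene, as whole numbers for 17611 genes in 18 libraries, in the column layout that featureCounts writes (gene identifier, exon coordinates, strand and length, per the file headers). Counts had not been normalised and replicates had not been pooled. Whether counting used strand, and how reads with several matches were treated, was not stated. Genes that overlap or lie antisense to each other, and members of multicopy families such as the histone genes and the Sdic genes, are therefore uncertain. Sequence differences between the lines and the reference could change how many reads of a gene were counted in a line, and this was not checked, since no reads were used here.

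Gene symbols were taken from the Ensembl BDGP6.54 annotation by gene identifier, and 17556 identifiers matched. Of these, 17540 had the same chromosome, start and end in the count table as in that annotation. Coordinates are those of the count table, counted from 1.

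Total counts ranged from 14352846 to 21343992 per library. No count was found for 2995 genes. Libraries were scaled by TMM, and 9037 genes passed the filterByExpr function of edgeR. A robust quasi-likelihood model of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) was fitted to all 18 libraries with 1 mean per group and no covariate, which left 12 residual degrees of freedom (common biological coefficient of variation 0.0973). The comparisons were diapause against reproductive, diapause against age control and reproductive against age control within each line, LP against HP within each state, and the differences between lines in the diapause effects (interaction contrasts). Genes were called at an adjusted p (Benjamini-Hochberg over the 9037 genes) under 0.05. Each adjusted p of a gene is from this test unless another tool is named. Fold changes are log2 values with their standard error (SE), and levels are TMM-scaled CPM as mean ± SD over 3 libraries. Genes called in the same direction in both the diapause against reproductive and the diapause against age-control comparison of a line are termed diapause-specific. The term does not mean that they were unchanged between reproductive and age-control ovaries.

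Gene lists, 40 in number with 845 symbols, were fixed before the data were examined, as were the comparisons, the tests, most of the alternatives and the rule for named genes. No gene was found for 9 of the symbols. The list of histone methyltransferases also holds subunits and partners without that activity (ash2, wds, Rbbp5, Dpy-30L1, Cfp1, Wdr82 and Mnn1), and that of histone demethylases holds the corepressor CoRest and JmjC proteins such as JMJD6 whose substrates are less clear. In 8 comparisons the 39 lists with at least 5 tested members were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The 312 p-values were adjusted together. Of the 90 list calls, 0 hold when the correlation is estimated from the data, a setting under which 0 of all 312 tests passed. List medians are over the tested members, and the counts of members adjusted over the list alone come from the same edgeR p-values.

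Named genes followed a rule. For each comparison it took the 5 called genes with the largest increase and the 5 with the largest decrease, among genes with a symbol that marks neither an unnamed nor a non-coding gene, at least 5 CPM in the higher group and no overlap between the groups' 3 libraries. For comparisons within a line it added up to 4 called members of each list that passed, up to 4 members of each of the histone methyltransferase and demethylase lists, and always Yp1, Yp2, Yp3, vas, bam, eya, cpo, tim, foxo, Kr-h1, Set1, Set2, Kdm5 and Kdm4A. Groups of 3 and 3 fail to overlap by chance in 10% of genes. The results of 1 gene that the rule names are not reported here. Genes named in the text outside this rule are said there to have been chosen after their values were seen.

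For genes with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of scaled counts is given with its exact 95% interval from the binomial distribution. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. Correlations of fold changes between comparisons, and Fisher's exact test of an overlap, are across genes, which are not independent replicates. For comparisons that share libraries, 20 simulations without any effect gave the overlap, correlation and covariance to compare with. Few genes are called without an effect, so the simulated overlap was bound to lie near 0. Adjacent called genes were counted over 9010 pairs of neighbouring tested genes and compared with 10000 shuffles of the calls.

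The alternatives were total counts as scaling, DESeq2 size factors in edgeR, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, a fit to only the groups compared, a test against a 1.5-fold change (glmTreat), the replicate number as a block, each library left out in turn, an estimated correlation or fry in place of the preset correlation, and for neighbours the removal of overlapping or similarly named pairs. An alternative chosen after the data were seen left out 3 libraries together, which were LP diapause replicate 2 (eggshell share), HP reproductive replicate 3 (principal component 4) and LP age-control replicate 2 (genes detected). The replicate numbers were not treated as pairs.

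The test was also run on simulated data for HP diapause against reproductive ovaries, with 200 of 9037 genes changed in 10 simulations. It recovered 29% of genes changed 1.25-fold, 62.8% of those changed 1.5-fold, 71.4% of those changed 2-fold and 88.8% of those changed 4-fold, with 4.8 false calls among 130.8 on average. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.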

Results

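Gene expression was measured in ovaries, given as stages 1 to 7, of 2 inbred lines of Drosophila melanogaster, HP and LP, in diapause at 12 °C, in reproductive flies at 12 °C and in 28-day-old age controls at 25 °C. Each of the 6 groups held 3 libraries. Total counts per library ranged from 14352846 to 21343992, and 9037 of 17611 genes were tested. The series, whose subject is histone methylation in diapause, sets diapause against both control states in a line termed high plasticity (HP) and a line termed low plasticity (LP).

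The first principal component held 47.3% of the variance and ran from the age controls at 25 °C through the reproductive to the diapause ovaries. The second held 26.4% and separated the lines. Eggshell genes, which follicle cells switch on in egg chambers older than those given in the labels, took 0.108% ± 0.0066 of the counts in HP diapause ovaries, 0.27% ± 0.05 in HP reproductive and 0.852% ± 0.25 in HP age-control ovaries (SD, n = 3 each). In the LP line these shares were 0.274% ± 0.16, 0.662% ± 0.062 and 1.7% ± 0.25. LP diapause replicate 2 stood apart from its group with 0.456%. Markers of muscle, which sheathes the ovary, took 0.313% ± 0.012, 0.279% ± 0.0059 and 0.165% ± 0.012 in the same order in HP. They took 0.292% ± 0.019, 0.245% ± 0.023 and 0.237% ± 0.02 in LP. Haemocyte markers took 0.262% ± 0.024, 0.233% ± 0.013 and 0.132% ± 0.013 in HP. They took 0.221% ± 0.028, 0.185% ± 0.0048 and 0.0898% ± 0.0081 in LP. These shares moved with the groups compared below, beside the gene lists described there.

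**Figure D1:**
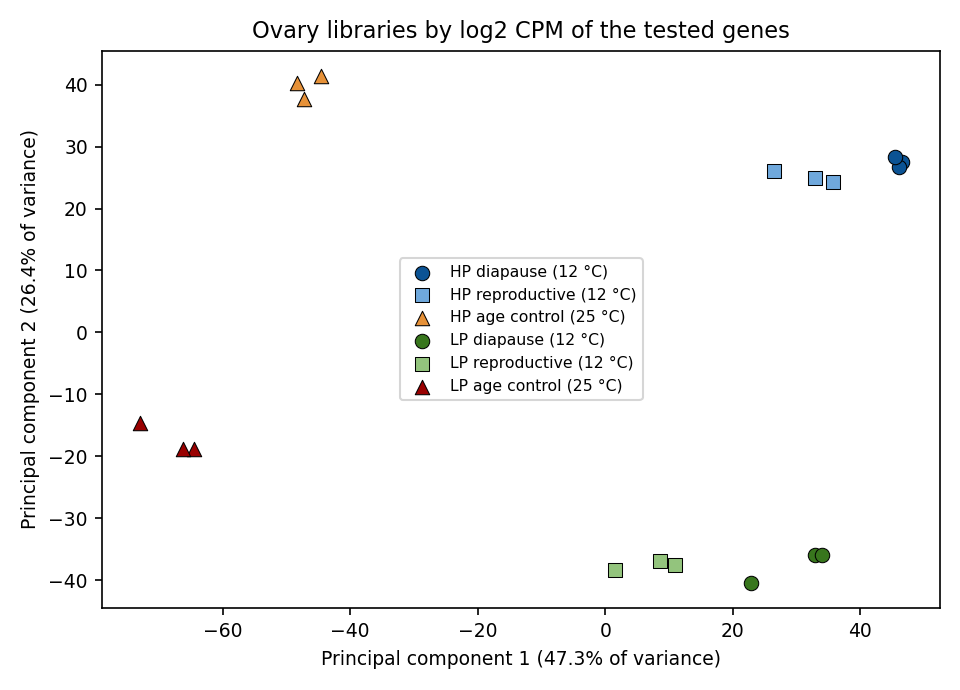
First and second principal components of log2 CPM of the 9037 tested genes for the 18 libraries, with the percent of variance on each axis; colour marks the group and shape the state. The 3 libraries of a group lie together, the first component (47.3%) runs from age control to diapause, and the second (26.4%) separates HP from LP.

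**Figure D2:**
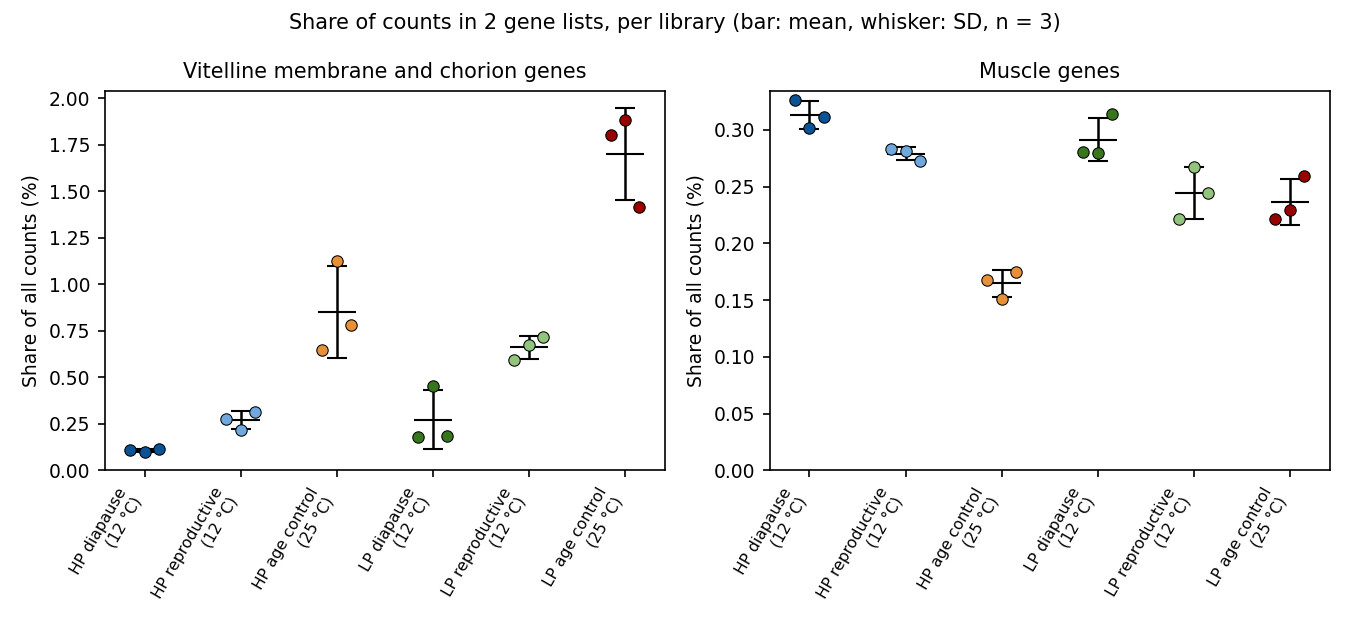
Percent of the counts of each library taken by vitelline membrane and chorion genes (left) and muscle genes (right) in the 6 groups; points are libraries, and bars and whiskers the mean and SD of 3. The eggshell share was lowest in diapause (0.108% in HP, 0.274% in LP) and highest in age controls (0.852% and 1.7%), and the muscle share was highest in diapause (0.313% and 0.292%).

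Diapause ovaries of the HP line had less of some eggshell and germline transcripts than reproductive ovaries, both from 12 °C. The vitelline membrane genes Vm34Ca and Vm26Aa fell in diapause. Vm34Ca went from 259 ± 55.7 to 19.2 ± 5.52 CPM (SD, n = 3 each; log2 fold change −3.74, SE 0.72, adjusted p = 0.043). Vm26Aa went from 585 to 152 ± 29.7 CPM (−1.94, SE 0.36, adjusted p = 0.037). The germline stem cell regulator nanos (3R, 19157238 to 19160202), a translational repressor, fell from 157 ± 15.1 to 106 ± 0.533 CPM (−0.57, SE 0.10, adjusted p = 0.014). The gene otu, a germline deubiquitinase, fell by 0.30 on the log2 scale (SE 0.06, adjusted p = 0.032). Hr4 (X, 1941940 to 2007956), a nuclear receptor of the ecdysone response, fell from 11.8 ± 1.09 to 4.04 ± 1.09 CPM (−1.52, SE 0.23, adjusted p = 0.0064). Pgant2 (2L, 3404460 to 3426719), an enzyme of O-glycosylation, rose from 7.18 ± 0.497 to 13.6 ± 2.5 CPM (0.92, SE 0.15, adjusted p = 0.0075).

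In this comparison 77 of the 9037 genes were called, 18 higher and 59 lower in diapause, and 11 changed over 2-fold. The other genes with the largest increase were Ndae1, a sodium-driven anion exchanger (1.04, SE 0.23), and His2B:CG33868, a histone gene with many near-identical copies and thus uncertain (1.03, SE 0.21). Next came the syntrophin-like Syn1 (0.65, SE 0.15) and the immunoglobulin-family gene bdl (0.56, SE 0.12). Cda5, related to chitin deacetylases, fell by 1.12 (SE 0.19) and the cytochrome P450 gene Cyp4s3 fell by 1.06 (SE 0.24). Of the 24 eggshell genes tested, 2 fell (13 adjusted over the list alone; median −3.07, adjusted p = 1.2e-13). Cytosolic ribosomal protein genes were shifted up together, by a median of 0.24 (adjusted p = 3e-27), although 0 of 88 passed singly over all genes and 74 adjusted over the list alone. Lists of oxidative phosphorylation (median 0.11, adjusted p = 8.6e-08), mitochondrial ribosomal proteins (0.09, adjusted p = 5.7e-06) and translation factors (0.09, adjusted p = 2.9e-05) were also shifted up, with 0 called members each. Muscle markers were shifted up by a median of 0.31 (0 of 25 called, 2 adjusted over the list alone, adjusted p = 1.6e-05). Haemocyte markers were shifted up by 0.26 (1 of 13 called, 1 adjusted over the list alone, adjusted p = 0.034). The called member was SPARC, a basement membrane protein that other cells also make (0.37, SE 0.08).

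Mitotic cell cycle genes were shifted down by a median of 0.12 (0 of 45 called, 6 lower and 1 higher adjusted over the list alone, adjusted p = 3.8e-05). DNA damage genes were shifted down likewise (median −0.10, 0 of 37 called, 5 adjusted over the list alone, adjusted p = 0.0006). Polycomb and trithorax group genes (median −0.12, 0 of 26 called, adjusted p = 0.016) were also shifted down. Germline stem cell genes followed (median −0.08, 2 of 23 lower, 3 lower and 1 higher adjusted over the list alone, adjusted p = 0.024). Yolk genes were shifted down as a list (median −0.55, 0 of 5 called, 3 adjusted over the list alone, adjusted p = 0.0074). Singly, Yp1 (525 ± 38.5 to 297 ± 21.1 CPM, −0.82, adjusted p = 0.074), Yp2 (−0.55, adjusted p = 0.13) and Yp3 (−0.82, adjusted p = 0.11) did not pass. The sugar metabolism list was shifted down by its test (adjusted p = 0.024) with a median of −0.08 and a mean of 0.02, so that the mean had the other sign. Of its members 0 of 27 were called (1 adjusted over the list alone). With an estimated correlation all 13 list calls were lost (adjusted p = 0.80 with an estimated correlation for Polycomb and trithorax, 0.79 for the others). Of the histone methyltransferase list 0 of 22 genes and of the demethylase list 0 of 14 were called by edgeR, and the lists did not pass (medians −0.10 and −0.06, adjusted p = 0.38 and 0.18). The smallest p-values among them belonged to the methyltransferase genes G9a (−0.23, adjusted p = 0.13) and egg (−0.20, adjusted p = 0.19), to the demethylase gene Utx (−0.19, adjusted p = 0.11) and to JMJD6, a JmjC protein gene (0.16, adjusted p = 0.18). Markers of fat body (median −0.20), oviduct (−0.02) and neurons (−0.11) did not pass. The germline genes vas (0.00) and bam (−0.25), the clock gene tim (0.26), cpo (0.01), eya (0.23), foxo (0.00), Kr-h1 (−0.50), Set1 (−0.04), Set2 (−0.09), Kdm5 (−0.15) and Kdm4A (−0.20) were not called.

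The count of genes called in HP fell whichever of the 6 libraries was left out. Without HP diapause replicate 1, 2 or 3 it was 9, 15 and 12, and without HP reproductive replicate 1, 2 or 3 it was 7, 45 and 9. Of the 13 named called genes 12, 9, 10, 11, 7 and 12 lost their call in these fits, and only Hr4 kept it in all 6. With total counts 13.7% of the called genes were higher in place of 23.4%. The count was 117 with total counts, 48 without a filter, 317 with DESeq2, 672 in a fit to these 6 libraries, 0 against a 1.5-fold change and 25 without the 3 libraries that stood apart.

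In the LP line, diapause ovaries had less of some chorion and cell division transcripts than reproductive ovaries of the same temperature. The chorion gene Cp19 fell from 56.3 ± 50.5 to 0.405 ± 0.125 CPM (−7.09, SE 1.19, adjusted p = 0.026). Cp7Fb, another, fell from 177 ± 166 to 2.49 ± 2.78 CPM (−6.13, SE 1.33, adjusted p = 0.048; SD, n = 3 each). Without LP reproductive replicate 3 Cp19 was −6.12 (adjusted p = 0.054), and its call was lost in 4 of 6 fits with 1 library left out. Cp7Fb was −7.65 without LP diapause replicate 2 and −5.06 without LP reproductive replicate 1, and its call was lost in all 6. The actin-bristle gene jv fell from 5.31 ± 1.42 to 1.6 ± 0.176 CPM (−1.72, SE 0.24, adjusted p = 0.0023). The cell cycle genes aurA, which encodes Aurora A kinase, and stg, a phosphatase that drives entry into mitosis, fell by 0.41 and 0.30. Falls of mad2, of the spindle checkpoint (−0.47), and cort, a meiotic activator of the anaphase-promoting complex (−0.41), passed too.

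Of 9037 genes 131 were called, 31 higher and 100 lower in diapause, and 19 changed over 2-fold. The largest increases were in mthl2, a G protein-coupled receptor gene (2.54 ± 0.171 to 5.15 ± 1.07 CPM, 1.02, SE 0.24, adjusted p = 0.045), and Jhbp7, named as a hormone-binding protein (1.00, SE 0.21). Next came the neprilysin gene Nep1 (0.71, SE 0.16), the complex I gene ND-18 (0.62, SE 0.14) and the tetraspanin gene Tsp42Eg (0.61, SE 0.13). Nha1, a sodium/proton antiporter gene, fell by 1.76 (SE 0.37; −2.76 without LP diapause replicate 1). Eggshell genes were shifted down (median −4.04, 3 of 24 lower, 19 adjusted over the list alone, adjusted p = 5.8e-18), among them ndl, an eggshell protease gene (−0.69). Mitotic cell cycle genes followed (median −0.24, 9 of 45 lower, 26 adjusted over the list alone, adjusted p = 2.7e-16). DNA replication genes were shifted down (−0.14, 1 of 35 lower, 10 adjusted over the list alone, adjusted p = 7.1e-10), among them the ribonucleotide reductase gene RnrL (−0.29). DNA damage genes were shifted down (−0.12, 2 of 37 lower, 9 adjusted over the list alone, adjusted p = 2.9e-05), with the mismatch repair gene Msh6 (−0.38) and the helicase gene mus301 (−0.37). Polycomb and trithorax genes were shifted down slightly (median −0.08, 0 of 26 called, adjusted p = 0.042).

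Ribosomal protein genes were shifted up (median 0.15, 1 of 88 called, 10 adjusted over the list alone, adjusted p = 9.5e-16). The called gene was RpL34b (0.41). Oxidative phosphorylation (median 0.08, 1 of 69 called, 2 adjusted over the list alone, adjusted p = 7e-05) and translation factors (0.08, 0 of 42 called, adjusted p = 0.00014) were also shifted up. Muscle markers were shifted up by a median of 0.57 (1 of 25 called, 16 adjusted over the list alone, adjusted p = 1.2e-10), with the sarcomere gene Zasp52 called (0.32). Haemocyte markers were shifted up by 0.36 (1 of 13 called, SPARC at 0.36, 2 adjusted over the list alone, adjusted p = 0.00055), and early follicle and escort cell genes by 0.22 (1 of 17 higher, Fas2 at 0.38, and 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.035). With an estimated correlation all 11 list calls were lost (adjusted p = 0.88 with an estimated correlation for oxidative phosphorylation, 0.86 for Polycomb and trithorax, 0.79 for the others). By edgeR 0 of 22 genes of the methyltransferase list and 0 of 14 of the demethylase list were called, and the lists did not pass (medians −0.07 and −0.05, adjusted p = 0.38 and 0.32). The smallest p-values there were those of Mnn1, a partner of methyltransferases (−0.19, adjusted p = 0.16), NSD (−0.18, adjusted p = 0.32), Kdm4A (−0.24, adjusted p = 0.13) and Su(var)3-3 (−0.22, adjusted p = 0.21). Not called either were Yp1 (−0.54), Yp3 (−0.70; −0.97, adjusted p = 0.027, without LP diapause replicate 2), bam (−0.31), tim (0.27), eya (0.27), cpo (0.02), foxo (0.09), Kr-h1 (0.15), Set1 (0.09), Set2 (0.00), Utx (−0.14) and Kdm5 (−0.17).

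Without LP diapause replicate 1, 2 or 3, 11, 279 and 6 genes were called, and without LP reproductive replicate 1, 2 or 3, 14, 17 and 21. Of the 22 named called genes 19, 2, 20, 19, 17 and 17 lost their call in these fits, and 2, jv among them, kept it in all 6. The count was 447 with DESeq2, 262 in a fit to these 6 libraries and 1 against a 1.5-fold change. With total counts 13.2% of the called genes were higher in place of 23.7%.

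**Figure D3:**
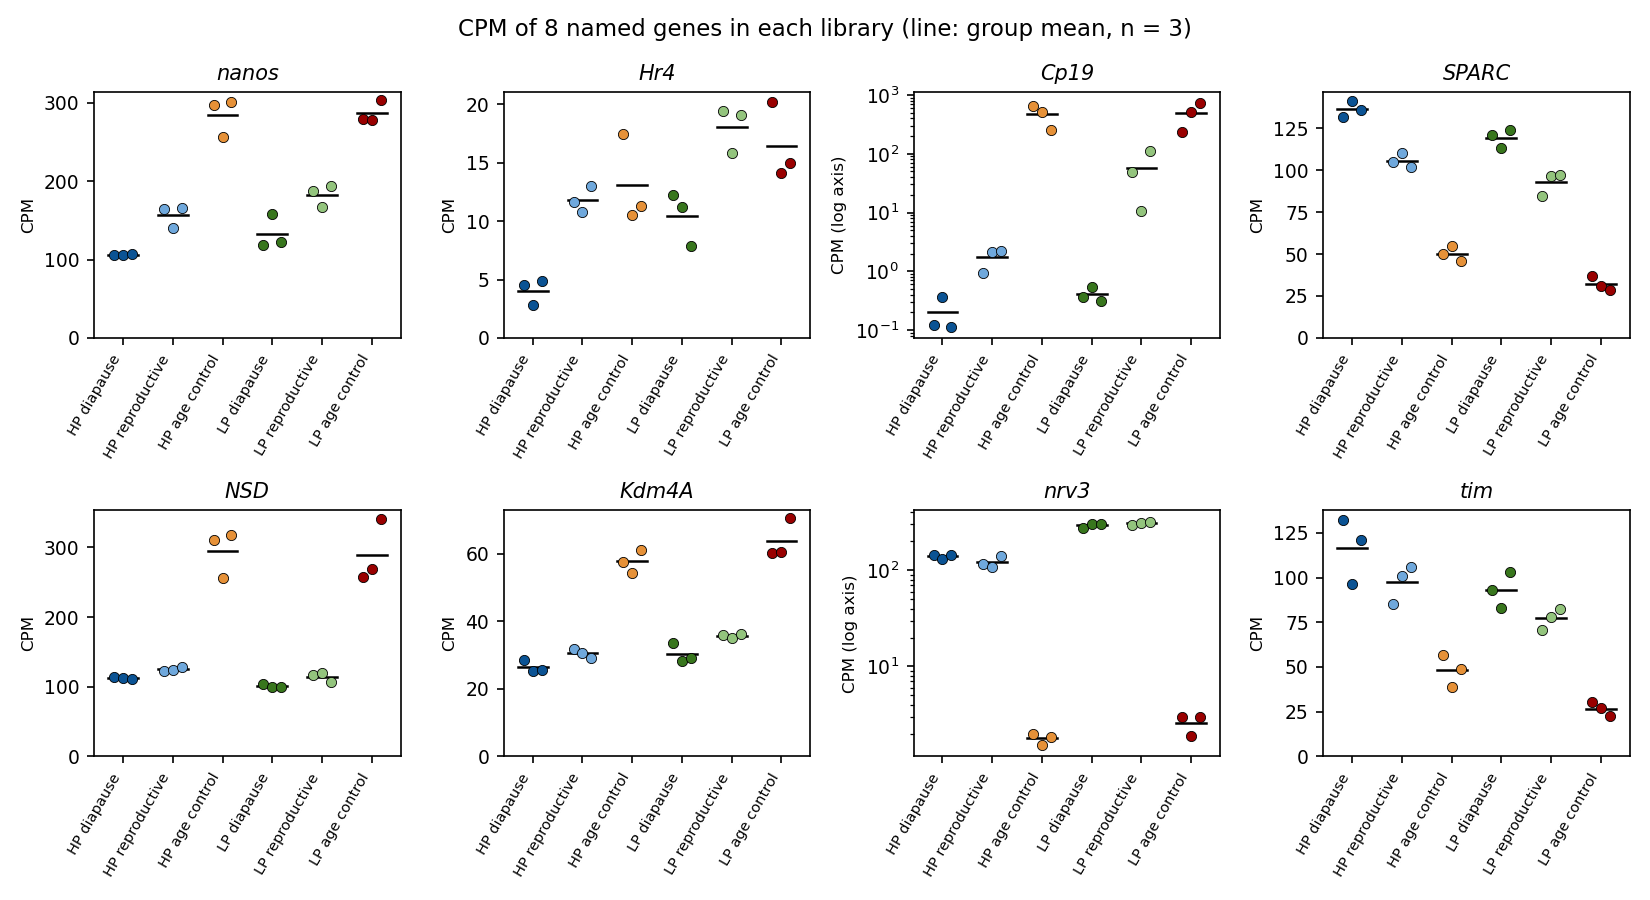
TMM-scaled CPM of nanos, Hr4, Cp19, SPARC, NSD, Kdm4A, nrv3 and tim in the 18 libraries by group, on a log axis for Cp19 and nrv3; points are libraries and lines the mean of 3. In HP, nanos lies at 106 CPM in diapause and 157 in reproductive ovaries, and nrv3 at 140 CPM in diapause and 1.79 in age-control ovaries.

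The same 17 genes were called between diapause and reproductive ovaries in both lines, all in the same direction, where independent lists would share 0.715. Fisher's exact test across genes, which are not independent replicates, gave p = 4.51e-16. Those of the 17 named here were chosen after their values were seen, except those named by the rule. SPARC was higher in diapause by 0.37 in HP and 0.36 in LP, and the other 16 were lower. Among these were nanos (−0.57 and −0.45) and retn, a DNA-binding gene (−0.40 and −0.33). Others were Lsd-2, which encodes a lipid droplet protein (−0.41 in both), the acyl-CoA synthetase gene bgm (−0.52 and −0.80), the kinesin gene cmet (−0.46 and −0.48), the chaperone gene Hsc70-3 (−0.36 and −0.27) and the tubulin ligase gene TTLL5 (−0.36 and −0.30). Others again were Marf1 (−0.39 and −0.26), mus302 (−0.37 and −0.39), cdi (−0.33 and −0.31), CG4842 (−0.88 and −0.70), CG11034 (−0.87 and −0.71), CG33090 (−0.33 and −0.32), CG32795 (−0.29 and −0.31) and CG1440 (−0.24 and −0.22). Over all tested genes, fold changes of the lines correlated at r = 0.353 across genes (covariance 0.105). Of the genes called in HP 93.5% had the same sign in LP, and of those called in LP 94.7% had it in HP. In reproductive against age-control ovaries, a comparison without diapause, 81.8% of the genes called in HP had that sign in LP. Of the genes called in LP, 92.4% had it in HP, so the changes were not confined to diapause. Without HP diapause replicate 1, 2 or 3 the shared count was 1, 3 and 3, without HP reproductive replicate 1, 2 or 3 it was 1, 8 and 1. Without LP diapause replicate 1, 2 or 3 it was 0, 53 and 4, and it was 2 without each LP reproductive library. It was 109 with DESeq2, 126 in fits to the 6 libraries of each line, 31 with total counts and 0 against a 1.5-fold change.

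Whether the diapause response at 12 °C differed between the lines was tested directly. By edgeR 0 genes differed in it, and 6 were called by DESeq2. At an unadjusted p under 0.05 by edgeR were 366 of 9037 genes, a share below the 0.05 that chance alone would give. Lists of DNA replication (median −0.14, adjusted p = 1.5e-08), mitotic cell cycle (−0.10, adjusted p = 6e-06), ribosomal proteins (−0.08, adjusted p = 0.0074) and mitochondrial ribosomal proteins (−0.04, adjusted p = 0.023) were lower in the LP than in the HP response. Muscle (0.15, adjusted p = 0.031) was higher. In each of the 5 lists 0 members were called. All 5 list calls were lost with an estimated correlation (adjusted p = 0.79, 0.79, 0.93, 0.89 and 0.84 with an estimated correlation). With fry 0 of 39 lists passed.

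**Figure D4:**
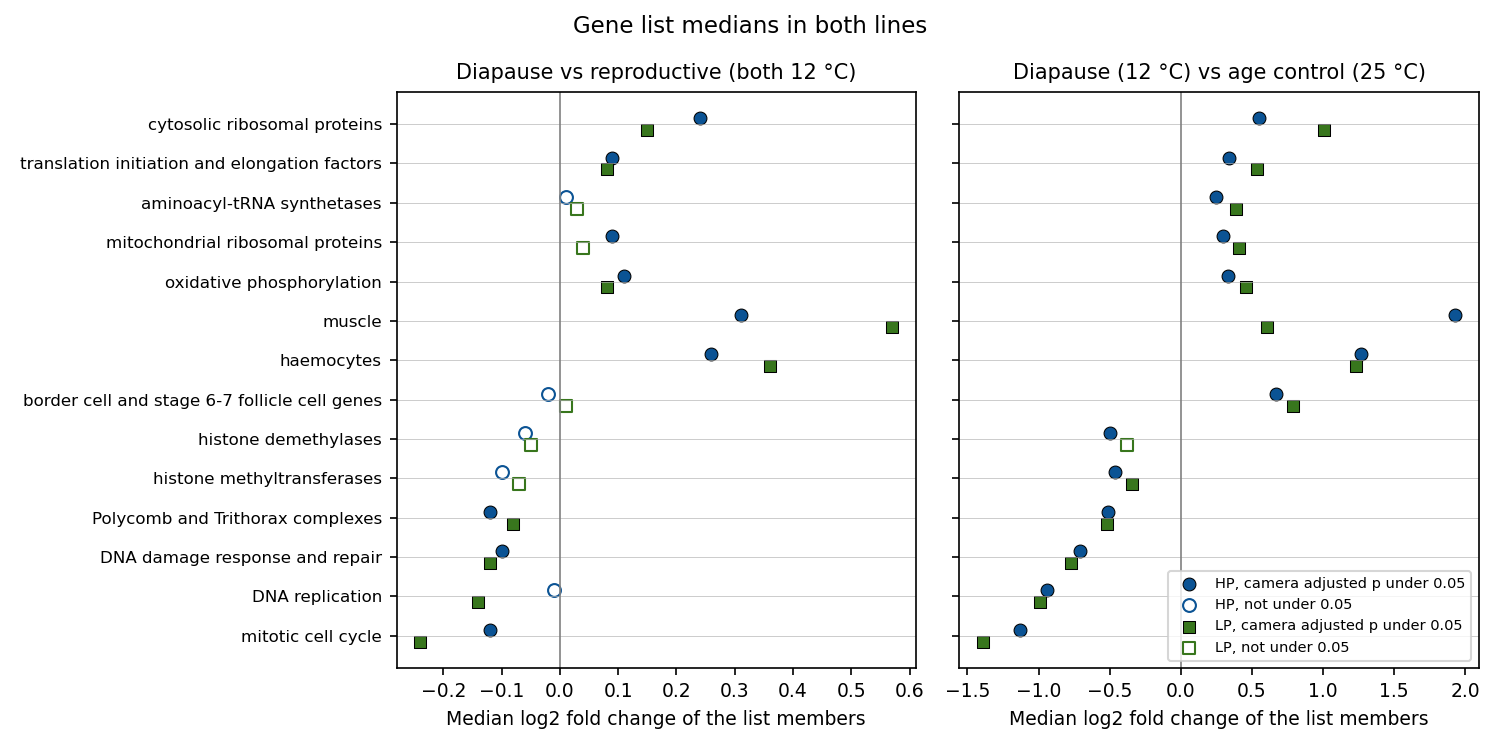
Median log2 fold change of the members of 14 gene lists in diapause against reproductive (left) and age-control ovaries (right), with circles for HP and squares for LP, filled where the camera adjusted p was under 0.05. Ribosomal protein medians were 0.24 and 0.15 at left and 0.55 and 1.01 at right, and mitotic medians −0.12 and −0.24 at left and −1.13 and −1.39 at right, in HP and LP; all the list calls shown were lost with an estimated correlation.

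Against age controls at 25 °C, HP diapause ovaries expressed more of the ribosomal, translation and muscle genes and less of the cell division, DNA repair, Polycomb and eggshell genes. The sodium pump subunit gene nrv3 rose from 1.79 ± 0.251 to 140 ± 7.37 CPM (6.28, SE 0.14, adjusted p = 2.7e-17; SD, n = 3 each), and dao from 4.08 ± 0.41 to 117 ± 13.6 CPM (4.84, SE 0.12). The chorion gene Cp19 fell from 471 ± 202 to 0.2 ± 0.145 CPM (−11.24, SE 1.24) and Cp16 from 267 ± 114 to 0.188 ± 0.173 CPM (−10.43, SE 1.96). Without HP diapause replicate 2 Cp19 was −11.90, and without HP diapause replicate 1 Cp16 was −9.82. Without HP diapause replicate 3 Cp16 had 3 counts left in diapause, a ratio of 2710 (95% interval 926 to 13100). NSD, a histone methyltransferase gene, fell from 295 ± 34.2 to 113 ± 1.52 CPM (−1.39, SE 0.09, adjusted p = 1.1e-10), and the histone demethylase gene Kdm4A from 57.8 ± 3.42 to 26.5 ± 1.86 CPM (−1.13, SE 0.08, adjusted p = 2.4e-10). Temperature differed together with diapause here, since the age controls were kept at 25 °C.

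Of 9037 genes 6203 were called, 3069 higher and 3134 lower in diapause, and 1866 changed over 2-fold. Scaling by total counts lowered the median fold change of all genes by 0.14 and left 38.6% of the called genes higher in place of 49.5%, so that directions are relative to the scaling. Against a 1.5-fold change 2341 genes were called. The other largest increases were in Phlpp, a phosphatase gene (5.22, SE 0.28), spirit, a serine protease gene (4.76, SE 0.38), and gNacalpha, a germline subunit of a nascent chain complex (4.39, SE 0.37). The mucin-type genes Muc4B, Muc12Ea and Mur11Da, the last also a member of the eggshell list, had 0 counts in diapause. They were at least 551-fold, 297-fold and 213-fold lower than in age controls (34.5 ± 10.9, 18.6 ± 9.52 and 13.4 ± 6.85 CPM). Without HP diapause replicate 1 or 3 these bounds were 359 and 349 for Muc4B, 193 and 188 for Muc12Ea, and 139 and 135 for Mur11Da.

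Ribosomal protein genes rose as a group (86 of 88 higher, median 0.55, adjusted p = 1.2e-13), with RpS14b (0.79), RpS26 (0.81), RpL41 (1.08) and RpL19 (0.61). Translation factors (33 of 42 higher and 2 lower, median 0.34, adjusted p = 3e-06) rose with eIF6 (1.13), eIF3d1 (0.78) and eIF4A (0.60). Aminoacyl-tRNA synthetases (11 of 17 higher, median 0.25, adjusted p = 0.0052; 9 higher and 4 lower, median 0.10, with total counts) rose with SerRS (0.68) and HisRS (0.73). Mitochondrial ribosomal proteins (53 of 72 higher and 4 lower, median 0.30, adjusted p = 2.8e-06; 34 higher and 7 lower with total counts) and oxidative phosphorylation (52 of 69 higher and 2 lower, median 0.33, adjusted p = 5.7e-06) rose too. Mitotic cell cycle genes fell (42 of 45 lower, median −1.13, adjusted p = 6.5e-14), with the condensin genes barr (−1.87, SE 0.09) and Cap-D2 (−1.84), CycB3 (−1.74) and stg (−1.15). DNA replication genes fell (32 of 35 lower, median −0.94, adjusted p = 1e-10), with Orc2 (−1.88), Orc4 (−1.48), Cdc6 (−1.70) and RnrL (−1.38). DNA damage genes fell as well (30 of 37 lower and 3 higher, 4 higher adjusted over the list alone, median −0.71, adjusted p = 7.5e-07). Among these were the nuclease gene mus81 (−1.89), Msh6 (−1.51), mus301 (−1.65) and the Ku subunit gene Irbp (−1.56). Eggshell genes fell (23 of 24 lower and 1 higher, median −7.39 and −7.27 with genes at 0 counts at their bound, adjusted p = 1.9e-05), among them Vm34Ca (−4.62) and Vm26Aa (−2.48).

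Polycomb and trithorax group genes fell in 25 of 26 cases (median −0.51, adjusted p = 1.4e-05), with phol (−1.10), esc (−1.04), caly (−1.02) and polybromo (−0.87). The histone methyltransferase list was lower (16 of 22 lower and 2 higher, 17 and 2 adjusted over the list alone, median −0.46, adjusted p = 0.011), with egg (−0.79), Smyd3 (−0.74) and Wdr82, a subunit of a methyltransferase complex (−0.78), beside NSD. The histone demethylase list was lower (9 of 14 lower and 1 higher, median −0.50, adjusted p = 0.042), with Su(var)3-3 (−0.89), its corepressor partner CoRest (−0.62) and Utx (−0.58). Muscle markers rose (22 of 25 higher and 1 lower, median 1.93, adjusted p = 3.9e-08), with Mlc2 (24.2 ± 4.03 to 233 ± 10.2 CPM, 3.27), Act87E (3.12), Mf (1.71) and Zasp52 (0.97). Haemocyte markers rose (8 of 13 higher and 1 lower, median 1.27, adjusted p = 0.024), with Pxn (2.21), SPARC (1.44) and the collagen IV genes Col4a1 (1.43) and vkg (1.16). Other cells also make SPARC, and the share of haemocytes themselves was not measured. The list of border cell and other follicle cell genes rose as well (14 of 21 higher and 3 lower, median 0.67, adjusted p = 0.049). Among these were shd, a gene of ecdysone synthesis (2.31), pnt (0.81), aos (1.11) and Mmp2 (1.5). With an estimated correlation all 15 list calls were lost (adjusted p = 0.84 with an estimated correlation for oxidative phosphorylation, 0.79 for the others). With total counts 14 lists passed in place of 15, and 14 with the replicate number as a block. The clock gene tim rose by 1.28, the RNA-binding gene cpo, linked to natural variation in diapause, by 0.74, eya by 0.72 and foxo by 0.25, a call that total counts ended (0.10, adjusted p = 0.23). The genes bam (−1.11), Set2 (−0.62), Kdm5 (−0.97), Yp1 (−0.71) and Yp3 (−1.04) fell. Yp2 (−0.24), Kr-h1 (−0.71) and Set1 (−0.14) were not called, but Set1 was without HP diapause replicate 1 (−0.17, adjusted p = 0.046) or HP age-control replicate 2 (−0.21, adjusted p = 0.0028), and Yp2 (−0.38) and Set1 (−0.29) were with total counts. The call of vas (−0.12, adjusted p = 0.026) was lost without HP diapause replicate 2 or 3 (adjusted p = 0.08 and 0.072) and without HP age-control replicate 1 or 3 (0.084 and 0.059).

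Against LP age controls, LP diapause ovaries expressed more of the ribosomal, translation and muscle genes and less of the cell division, DNA repair, Polycomb and eggshell genes. The sodium pump subunit gene nrv3 rose from 2.6 ± 0.625 to 293 ± 17.1 CPM (6.81, SE 0.13; SD, n = 3 each). The other largest increases were in dao, TkR86C, a tachykinin-type receptor gene (5.49, SE 0.74), DIP-iota (4.56, SE 0.39) and the acyl-CoA synthetase gene Acsx4 (4.01, SE 0.17). Without LP age-control replicate 3 TkR86C was 4.89, and without LP age-control replicate 2 it had 1 count left in age controls, a ratio of 288 (95% interval 51.4 to 11400). Cp15 fell from 1570 ± 141 to 1.44 ± 1.09 CPM (−10.09, SE 1.65), with the chorion genes Cp19 (−10.22, SE 1.11) and Cp16 (−9.74, SE 1.82). Without LP diapause replicate 2 Cp15 was −10.89 and Cp16 −10.53, and without LP age-control replicate 3 Cp16 was −8.70. Femcoat had 2 counts in diapause against 4117 in age controls, a ratio of 1640 (95% interval 454 to 13600), and Mur11Da 1 against 1472, a ratio of 1170 (210 to 46400). The ratio of Femcoat was 1050 (292 to 8710) without LP diapause replicate 1. That of Mur11Da was 775 (139 to 30600) without LP diapause replicate 2 and 668 (119 to 26400) without LP age-control replicate 3, and without LP diapause replicate 1 it had 0 counts and was at least 244-fold lower. Of 9037 genes 6502 were called, 3311 higher and 3191 lower. Of these 2240 changed over 2-fold, and 2888 were called against a 1.5-fold change. Scaling by total counts lowered the median by 0.23 and left 36% of the called genes higher in place of 50.9%.

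All 88 ribosomal protein genes rose (median 1.01, adjusted p = 6.1e-20), with RpS14b (1.40), RpL3 (1.14), RpS15Aa (1.10) and RpS3A (1.01). Translation factors (38 of 42 higher and 2 lower, median 0.54, adjusted p = 1.4e-08) rose with eIF4A (0.95), eIF3d1 (0.90) and eIF6 (1.17). Oxidative phosphorylation genes rose (64 of 69 higher and 1 lower, median 0.46, adjusted p = 1.6e-08), with Cyt-c1L (3.0). Mitochondrial ribosomal proteins (56 of 72 higher and 3 lower, median 0.41, adjusted p = 5e-07; 38 higher and 8 lower with total counts) and aminoacyl-tRNA synthetases (15 of 17 higher, median 0.39, adjusted p = 6.9e-05; 10 higher and 2 lower with total counts), with HisRS (1.02) and LeuRS (0.81), rose. Mitotic cell cycle genes (42 of 45 lower and 1 higher, median −1.39, adjusted p = 7.6e-14) fell, with fzy, an activator of the anaphase-promoting complex (−2.25), tum, needed for cytokinesis (−2.0), barr (−1.86) and stg (−1.23). DNA replication genes fell (34 of 35 lower, median −0.99, adjusted p = 1.2e-11), with Orc2 (−2.03), Mcm3 (−1.26), Mcm5 (−1.20) and RnrL (−1.34). DNA damage genes fell too (30 of 37 lower and 4 higher, median −0.77, adjusted p = 1.1e-06), with mus301 (−1.97), Irbp (−1.72), Msh6 (−1.67) and mus81 (−1.57). Eggshell genes fell (21 of 24 lower and 1 higher, median −6.35, adjusted p = 0.00015).

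Polycomb and trithorax genes fell (24 of 26 lower, median −0.52, adjusted p = 1.8e-05), with esc (−1.29), phol (−1.25) and mor (−0.66). The histone methyltransferase list was lower (13 of 22 lower and 2 higher, median −0.34, adjusted p = 0.036), with NSD (−1.52), egg (−0.81) and the complex subunits Cfp1 (−0.88) and Wdr82 (−0.75), while Smyd5 rose (0.82). The histone demethylase list did not pass (median −0.38, adjusted p = 0.23). Of its 14 genes 8 were lower and 2 higher, and the lower ones included Su(var)3-3 (−1.20), Kdm4A (−1.07), CoRest (−0.85) and Utx (−0.59). Muscle markers rose (19 of 25 higher, median 0.61, adjusted p = 0.0027; 15 higher and 3 lower with total counts), with Mlc2 (1.45), Zasp52 (0.61), Chd64 (0.59) and Mlc-c (0.52), of which the last is made in many cell types. Haemocyte markers rose (7 of 13 higher, median 1.23, adjusted p = 0.037; 7 higher and 1 lower with total counts), with Col4a1 (2.28), SPARC (1.90), vkg (1.87) and ush (1.13). Here too the share of haemocytes themselves was not measured. The list of border cell and other follicle cell genes rose (13 of 21 higher and 3 lower, median 0.79, adjusted p = 0.034), with shd (2.52), aos (1.76), peb (1.24) and pnt (1.09). With an estimated correlation all 14 list calls were lost (adjusted p = 0.79 with an estimated correlation for each). The genes tim (1.81), eya (1.62), foxo (0.55), cpo (0.40) and vas (0.28) rose, of which total counts ended the calls of cpo (0.18) and vas (0.06), and bam (−0.53), Kdm5 (−1.06) and Yp3 (−0.81) fell. Yp1 (−0.04), Yp2 (0.35), Set1 (−0.12) and Set2 (−0.18) were not called. Leaving out LP diapause replicate 1 gave a call of Yp2 (0.44, adjusted p = 0.045), LP diapause replicate 3 of Set2 (−0.26, adjusted p = 0.017) and LP age-control replicate 2 of Set1 (−0.16, adjusted p = 0.047), and total counts gave calls of Set1 (−0.35) and Set2 (−0.41). The rise of Kr-h1, a transcription factor gene of the juvenile hormone response (1.37, adjusted p = 0.012), was lost without LP age-control replicate 3 (adjusted p = 0.052).

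Reproductive ovaries at 12 °C differed from age controls at 25 °C in much the same genes, a comparison without diapause across the same temperatures. In HP 5900 genes were called, 2908 higher and 2992 lower, and in LP 6108, 3063 higher and 3045 lower. Over 2-fold changes were found for 1607 and 1725, and 1889 and 2203 were called against a 1.5-fold change. Again nrv3 (6.08 in HP, 6.88 in LP) and dao (4.85 and 6.53) were among the named genes that rose most. The others were Phlpp (5.43), spirit (4.46) and DIP-iota (4.23) in HP and DIP-iota (4.30), gNacalpha (4.06) and scpr-C (3.87) in LP. In LP gNacalpha was 4.90 without LP age-control replicate 2. In HP the chorion genes Cp16 (−9.32), Cp18 (−8.29) and Cp19 (−8.07) and Femcoat (−7.73) fell most, and Mur11Da was lower by a ratio of 746 (95% interval 133 to 29500; 470, 84.2 to 18600, without HP reproductive replicate 2, and at least 174-fold without HP reproductive replicate 3). Without HP reproductive replicate 3 Cp16 was −10.31, and without HP age-control replicate 2 Cp18 was −7.49. Without HP reproductive replicate 2 Femcoat had 2 counts left in reproductive ovaries, a ratio of 427 (118 to 3530). In LP S-Lap1 (−5.64), Cp7Fa (−4.36), tbc (−4.05) and Cp15 (−3.92) fell most, of which Cp15 was −6.45 and Cp7Fa −5.29 without LP reproductive replicate 3 and S-Lap1 −3.27 without LP age-control replicate 2. They stood beside Mur18B (−7.17, adjusted p = 0.028). The call of Mur18B was lost without each LP reproductive library (adjusted p = 0.066, 0.079 and 0.077 for replicates 1, 2 and 3) and without LP age-control replicate 1 (−2.01, adjusted p = 0.53). Scaling by total counts lowered the medians by 0.11 and 0.19 and left 39.3% and 35.4% of the called genes higher in place of 49.3% and 50.1%.

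The histone methyltransferase list was lower in reproductive than age-control ovaries of both lines (13 of 22 lower and 2 higher in each, medians −0.36 and −0.28, adjusted p = 0.018 and 0.032), with NSD at −1.24 and −1.34. The demethylase list was lower in HP (10 of 14 lower and 2 higher, median −0.39, adjusted p = 0.047) and did not pass in LP (7 of 14 lower and 3 higher, median −0.36, adjusted p = 0.23). Kdm4A was at −0.92 in HP and −0.84 in LP, and Kdm5 at −0.82 and −0.89. Of the lists, 15 passed in HP and 11 in LP, and all of these calls were lost with an estimated correlation (adjusted p = 0.88 with an estimated correlation for oxidative phosphorylation and 0.84 for both ribosomal lists in HP, 0.79 for the others). In HP and LP respectively, 75 and 86 of 88 ribosomal protein genes were higher (medians 0.32 and 0.82; in HP 54 higher and 1 lower with total counts) and 43 and 42 of 45 mitotic genes lower and 1 and 2 higher (−1.02 and −1.14, with fzy at −1.79 and tum at −1.69 in LP). Of 26 Polycomb and trithorax genes 24 and 23 were lower (−0.39 and −0.49, with esc at −1.14 and phol at −0.91 in HP). Muscle markers were higher in HP (22 of 25, median 1.63). The eggshell list fell in HP (10 of 24 lower and 1 higher, 9 lower adjusted over the list alone, median −2.30, adjusted p = 0.027), a call that total counts ended (adjusted p = 0.081). The genes tim (1.02 and 1.54), eya (0.50 and 1.35) and cpo (0.73 and 0.39; 0.20 and not called in LP with total counts) rose in both lines, kek1 (2.13) and Yp2 (0.72) in LP, and bam (−0.85) and Set2 (−0.53) fell in HP. In HP Yp1 (0.12), Yp2 (0.31; 0.52, adjusted p = 0.011, without HP age-control replicate 2) and Yp3 (−0.22) were not called. By TMM scaling vas rose in LP (0.24 to 0.28 with 1 library left out, called in all 6 fits) and fell in HP. The call of vas in HP (−0.12, adjusted p = 0.026) was lost without HP reproductive replicate 1 or 3 (adjusted p = 0.059 and 0.079) or HP age-control replicate 1 or 3 (0.083 and 0.058). In LP that of Yp1 (0.50, adjusted p = 0.037) was lost without LP reproductive replicate 2 or 3 (0.078 and 0.12) or LP age-control replicate 3 (0.15), and that of Kr-h1 (1.22, adjusted p = 0.024) without LP reproductive replicate 2 or 3 (0.06 and 0.15) or LP age-control replicate 2 or 3 (0.081 and 0.088).

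Most genes that differed between diapause and age-control ovaries also differed between reproductive and age-control ovaries. In HP 5434 genes were called in both comparisons in the same direction and 0 in opposite directions, and in LP 5783 and 2. Independent lists would share 2030 and 2200. Both comparisons use the same 3 age-control libraries, so part of the excess may come from these, and the libraries are too few to split. Simulated data without effects gave an overlap of 0 genes in both lines, with correlations of 0.466 and 0.484 and covariances of 0.0556 and 0.0558. That overlap was bound to lie near 0, since few genes are called without an effect, so it does not measure the part due to shared libraries. The observed correlations were 0.898 in each line and the covariances 1.17 and 1.15. Diapause-specific genes, called against both controls in the same direction, numbered 67 in HP (14 higher and 53 lower) and 123 in LP (26 higher and 97 lower), with 26.6 and 46.7 for independent lists. In opposite directions 5 and 2 were called. Without HP diapause replicate 1, 2 or 3 the HP count was 9, 12 and 10, without HP reproductive replicate 1, 2 or 3 it was 6, 40 and 6, and without HP age-control replicate 2 it was 292. Without LP diapause replicate 1, 2 or 3 the LP count was 10, 261 and 6, without LP reproductive replicate 1, 2 or 3 it was 14, 15 and 18, and without LP age-control replicate 2 or 3 it was 66 and 258. Of the diapause-specific genes the same 17 as between diapause and reproductive ovaries were shared by the lines, among them nanos and SPARC, against 0.609 for independent lists. This count of 17 ranged from 0 without LP diapause replicate 1 to 58 without HP age-control replicate 2, and beyond the changes given for the genes called in both lines it was 49 without LP diapause replicate 2 and 6 and 42 without LP age-control replicate 2 or 3. These comparisons share the diapause libraries, and part of the excess may come from these. Without effects the simulated overlap was 0.05 and 0, the correlation 0.53 and 0.506 and the covariance 0.0659 and 0.0591. The simulations left out the difference to age controls as well, so this overlap too was bound to lie near 0 and does not measure that part. The observed correlations were 0.51 and 0.558 and the covariances 0.34 and 0.377.

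The lines shared 5093 genes called between diapause and age control in the same direction, 2465 higher and 2628 lower, where independent lists would share 2230. In opposite directions 145 were called. The change itself differed between the lines for 1661 genes, 1005 with a higher log2 fold change in LP and 656 with a lower one. Against a 1.5-fold difference 280 were called. With total counts 42.7% of them had the higher change in LP in place of 60.5%. Of the 1661 genes, 819 changed the same way in both lines, 316 were called in HP alone and 375 in LP alone. The immune enzyme gene PPO2 fell by 1.83 in HP. In LP it had 0 counts in age controls and 11 in diapause, at least 4.8-fold higher, which puts the log2 difference at 4.11 or more (adjusted p = 0.00041). The male germline gene tut (difference 3.40), Dscam4 (3.36), Hesr (3.22) and St3 (3.11) had the next largest differences upwards. Of these St3 was low in HP (0.355 CPM in diapause and 0.202 in age controls), and Dscam4 was low in LP (2.03 and 0.121 CPM). Arc1, a capsid-like gene, rose by 2.85 in HP and fell by 0.86 in LP (difference −3.71, SE 0.17, adjusted p = 1.1e-10). Phlpp rose by 5.22 in HP and 1.63 in LP (−3.59). The antimicrobial peptide gene Dro rose by 1.35 in HP and fell by 2.84 in LP (−4.19), with tbc at −4.06. In HP tbc was low in diapause and age-control ovaries (0.466 and 0.574 CPM).

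Ribosomal protein genes were shifted up in LP against HP (67 of 88 higher, 78 adjusted over the list alone, median difference 0.45, adjusted p = 5.8e-18). Shifted up likewise were the lists of translation factors (16 of 42 higher and 2 lower, 20 and 2 adjusted over the list alone, median 0.18, adjusted p = 0.00035), aminoacyl-tRNA synthetases (7 of 17 higher, 3 with total counts, median 0.16, adjusted p = 0.0029) and oxidative phosphorylation genes (4 of 69 higher, median 0.13, adjusted p = 0.016). Muscle markers were shifted down in LP against HP (19 of 25 lower and 1 higher in the difference, 20 and 1 adjusted over the list alone, median −1.28, adjusted p = 2.4e-10). The mitotic list was shifted slightly down (5 of 45 lower, 4 adjusted over the list alone, median −0.10, adjusted p = 0.024). All 6 list calls were lost with an estimated correlation (adjusted p = 0.91 with an estimated correlation for oxidative phosphorylation, 0.88 for mitotic genes, 0.79 for the others). S-Lap1, a sperm aminopeptidase gene, had the most negative difference. In HP it had 0 counts in age controls and 7 in diapause, and in LP 374 and 4, which puts the log2 difference at −7.91 or lower (adjusted p = 0.04). Its call was lost without HP diapause replicate 1, 2 or 3 (adjusted p = 0.063, 0.064 and 0.23), HP age-control replicate 1, 2 or 3 (0.059, 0.061 and 0.061) or LP diapause replicate 1, 2 or 3 (0.067, 0.069 and 0.071). The bound was −7.33, −7.31 and −7.32 without HP age-control replicate 1, 2 or 3 and −7.32 without LP diapause replicate 3, and without HP diapause replicate 3 no fold is given in HP, with 2 counts against 0. Without LP age-control replicate 2 it was at −5.54 or lower (adjusted p = 0.0052), and Dscam4 had 2 counts left in LP age controls against 111 in LP diapause, a ratio of 47.2 (95% interval 12.8 to 395). Without HP age-control replicate 2 St3 was 2.37 and without HP age-control replicate 3 tbc was −5.48. PPO2 was at 3.09 or more without LP diapause replicate 3 and at 3.47 or more without LP age-control replicate 3.

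LP and HP ovaries differed within each state, by 2947 genes in diapause (1570 higher and 1377 lower in LP), 3174 in reproductive (1666 and 1508) and 3782 in age-control ovaries (1801 and 1981). Of these 725, 763 and 1029 changed over 2-fold. In diapause the ubiquitin ligase gene SkpC had 12846 counts in LP and 3 in HP, a ratio of 3800 (95% interval 1300 to 18400). The glutathione transferase gene GstZ1 had 911 and 0, at least 270-fold higher, and the corazonin receptor gene CrzR 352 and 1, a ratio of 312 (55.6 to 12400). Lower in LP were the ammonium transporter gene Amt (2 counts against 305, ratio 172, 47.2 to 1430), Cyp6a9 (−6.45; a ratio of 199, 67.7 to 965, without LP diapause replicate 2), the cell adhesion gene Dscam4 (2.03 ± 0.576 against 95.9 ± 5.56 CPM, −5.54), the uncertain histone gene His2B:CG33868 (−4.97) and euc (−4.70; −5.39 without LP diapause replicate 3). The bound of GstZ1 was 176 and 171, and the ratio of CrzR 203 (36.2 to 8040) and 198 (35.2 to 7830), without HP diapause replicate 1 or 3. SkpC was at least 2480-fold higher without HP diapause replicate 1, with a ratio of 2400 (822 to 11700) without HP diapause replicate 3, and CrzR at least 74-fold without HP diapause replicate 2. Amt had a ratio of 111 (30.4 to 917) without LP diapause replicate 1 and was at least 75.6-fold lower without LP diapause replicate 2. Vm32E was higher in LP (5.39, adjusted p = 0.0074; 3.04 without LP diapause replicate 2 and 6.05 without HP diapause replicate 3), as was Vm26Ac (5.66, adjusted p = 0.029), whose call was lost without HP diapause replicate 1, 2 or 3 (adjusted p = 0.084, 0.079 and 0.085) and without LP diapause replicate 2 (1.34, adjusted p = 0.55).

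In reproductive ovaries SkpC (ratio 6440, 1780 to 53200), GstZ1 (438, 121 to 3620) and CrzR (6.16 on the log2 scale; a ratio of 129, 35.4 to 1070, without HP reproductive replicate 1) were again higher in LP. So were the chorion genes Cp18 (7.08, adjusted p = 0.022) and Cp16 (6.79, adjusted p = 0.014). The call of Cp18 was lost without HP reproductive replicate 1, 2 or 3 (adjusted p = 0.065, 0.073 and 0.07) and LP reproductive replicate 3 (3.61, adjusted p = 0.23), and that of Cp16 without HP reproductive replicate 2 (adjusted p = 0.052) and LP reproductive replicate 3 (4.33, adjusted p = 0.1), while Cp16 was 7.78 without HP reproductive replicate 3. Without HP reproductive replicate 2 SkpC and GstZ1 had 0 counts in HP and were at least 2690-fold and 184-fold higher. Lower were Amt (ratio 175, 48.2 to 1450; 114, 31.4 to 947, without LP reproductive replicate 3), Dscam4 (−6.46), Cyp6a9 (−6.33; a ratio of 181, 61.6 to 878, without LP reproductive replicate 3), pst (−4.45) and the cubilin gene Cubn2 (−4.01). In age controls SkpC (9.72), GstZ1 (ratio 341, 116 to 1650) and the septate junction gene Ssk (5.60) were higher in LP, with mthl8 (438 counts against 0, at least 139-fold) and S-Lap1 (374 against 0, at least 122-fold). Without LP age-control replicate 2 S-Lap1 had 49 counts against 0, at least 23.6-fold higher. Without HP age-control replicate 2 or 3 the bounds were 91.9 and 92.6 for mthl8 and 80.6 and 81.2 for S-Lap1. PPO2 had 0 counts in LP and 701 in HP age controls, at least 246-fold lower (158-fold without LP age-control replicate 3). The genes Dscam4 (−8.90; a ratio of 1360, 378 to 11300, without LP age-control replicate 2), the synaptic gene Fife (−6.51), Cyp6a9 (−5.92) and the calcineurin gene CanB (−5.01) were lower too. The line difference was shared between diapause and reproductive ovaries for 2245 genes, and between diapause and age-control ovaries for 1582, with 159 opposite. Against a 1.5-fold difference 554, 525 and 803 genes were called in diapause, reproductive and age-control ovaries, and with total counts 62.1% of the age-control calls were higher in LP in place of 47.6%.

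Called genes were also tested for lying next to each other on the chromosomes. In LP diapause against reproductive ovaries 5 adjacent pairs changed in the same direction against 1.17 by chance (permutation p = 0.0063), among them jv and ndl. In HP 2 pairs did against 0.442 by chance (permutation p = 0.071), and leaving out overlapping pairs gave p = 0.047. Against age controls 2282 pairs were called in HP and 2550 in LP against 2123 and 2335 by chance (permutation p = 1e-04 each, the smallest that 10000 shuffles can give).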

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

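The tests of library scaling and of single libraries, and that of muscle on genes with a higher change in LP, were chosen only after the result was seen.

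The change from diapause to age control differed between the lines, by a test of the difference itself, for 1661 genes, which set these results apart from the rest. The genes with the largest differences (LP minus HP, log2) were PPO2 (4.11 or more), tut (3.40), Dscam4 (3.36), Hesr (3.22) and St3 (3.11) upwards, and S-Lap1 (−7.91 or lower), Dro (−4.19), tbc (−4.06), Arc1 (−3.71) and Phlpp (−3.59) downwards, where genes with 0 counts in a group were set at the floor of 3 counts. S-Lap1 rested on LP age-control replicate 2, which held 325 of its 374 counts there (−5.54 or lower without it), and its call was lost in 9 of 12 fits with 1 library left out. Lists that differed were cytosolic ribosomal proteins (median 0.45), translation initiation and elongation factors (0.18), aminoacyl-tRNA synthetases (0.16), oxidative phosphorylation (0.13), mitotic cell cycle (−0.10) and muscle (−1.28), none of which passed with an estimated correlation (adjusted p = 0.79 to 0.91). Of the 1661 genes, 812 differed between the lines in age-control ovaries alone, 390 in diapause alone, 417 in both and 42 in neither.

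The count was 1653 at the lowest with other library scalings and 1321 at the lowest with 1 of the 12 libraries left out. This argues against scaling or a single library as the source of the count. The directions did depend on scaling, since with total counts 42.7% of the called genes had the higher change in LP in place of 60.5%. More muscle in the LP age-control dissections would lower the change in LP for muscle genes. It could raise the change for other genes, whose part of the counts would shrink. The genes with a higher change in LP, at the lowest 729 with any of 3 scalings, therefore cannot decide this. Of the called genes 4.1% correlated above 0.8 with the muscle mean over the 12 libraries at 12 °C. The muscle share differed little there (group means 0.245% to 0.313%), so the explanation stays open. As many genes were called in 7 of 100 splits of the libraries between lines (highest other split 2166), so chance was not excluded by this count, and the large counts came from splits that exchanged 2 libraries between the lines within 1 state, a structure that follows from the difference between the lines. A difference between the genotypes in the response, or in their age controls, stays open as untested.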

How the results depend on the processing

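The fits without 3 libraries that stood apart were chosen after the data were seen, and the other alternatives before. Over 433 results of named genes, 6098 of 6523 values under other settings kept their side of the threshold, 387 fell below it, 38 passed it newly and 0 reversed. A change of sign counted as a reversal only where the main or the other fit called the gene. Values called in neither fit could change sign uncounted. With another scaling, 0 of the lists that passed turned the sign of their median. For HP diapause against reproductive, LP diapause against reproductive, genes called in both lines, and diapause-specific genes of HP, LP and both lines, in this order, the main counts were 77, 131, 17, 67, 123 and 17. They were 317, 447, 109, 269, 415 and 101 with DESeq2, 672, 262, 126, 560, 248 and 122 in fits to only the groups compared, and 0, 1, 0, 0, 1 and 0 against a 1.5-fold change. With total counts the count was 117 for HP diapause against reproductive, 31 for both lines, 102 for HP diapause-specific genes and 30 for those of both lines. Without a filter it was 48 for HP diapause against reproductive and 41 for HP diapause-specific genes, and without the 3 libraries 25 and 21, where fewer libraries were used. Against a 1.5-fold change the counts were 2341 and 1889 for HP diapause and reproductive against age control, 2888 and 2203 for LP, 280 for the line difference, and 554, 525 and 803 for LP against HP in diapause, reproductive and age-control ovaries, where the hypothesis asks for more. The line difference between diapause and reproductive ovaries was 6 with DESeq2 and 0 with edgeR. With an estimated correlation 0 of 90 list calls were left. With fry, which tests a list's members without setting them against other genes, 132 of 312 tests passed. In HP and LP these were 4 and 7 for diapause against reproductive and 27 and 29 for diapause against age control. They were 27 and 28 for reproductive against age control. For the line differences they were 0 (diapause against reproductive) and 10 (diapause against age control). Neighbouring pairs in HP diapause against reproductive were 2 with permutation p = 0.047 without overlapping pairs, and 22 with p = 1e-04 (the smallest that the shuffles can give) from calls of DESeq2. Apart from the causes named, the cause was not tested.

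With 1 library left out the counts ranged from 7 to 45 for HP diapause against reproductive, 6 to 279 for LP, 0 to 53 for both lines, 6 to 292, 6 to 261 and 0 to 58 for the diapause-specific genes, and 0 to 1 for the line difference between diapause and reproductive ovaries. They ranged from 5819 to 6177 and 5358 to 5831 for HP diapause and reproductive against age control, 6122 to 6359 and 5671 to 5927 for LP, and 1321 to 1846 for the line difference. For LP against HP they ranged from 2325 to 2656, 2292 to 2717 and 3275 to 3805. The replicate numbers did not pair the libraries (same-numbered libraries of a line correlated at a median of −0.007, from −0.137 to 0.164, and 7 of 18 correlated best with their own number), and with the replicate number as a block 56, 110 and 15 genes were called for HP diapause against reproductive, LP and both lines, and 87 lists. Depth limits genes with few counts, such as the chorion genes in diapause.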

Other observations

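The test of somatic tissue and the fits without 3 libraries were chosen only after the results were seen.

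Several gene lists not yet described had members that moved in both directions against age controls and did not pass as lists. Of 24 meiosis and synaptonemal complex genes, 13 were lower in diapause in each line, with 4 higher in HP and 8 in LP (medians −0.66 and −0.85, adjusted p = 0.098 and 0.23). Of 13 clock and diapause-linked genes, 8 were higher and 5 lower in HP, and 9 higher and 3 lower in LP (medians 0.64 and 0.88, adjusted p = 0.48 and 0.15). Of 26 lipid genes, 8 were higher and 9 lower in HP and 14 higher and 4 lower in LP (medians 0.04 and 0.16, adjusted p = 0.85 and 0.24; −0.10 and −0.07 with total counts). Of 25 ecdysone genes, 13 were higher and 8 lower in HP and 14 higher and 7 lower in LP (medians 0.31 and 0.55, adjusted p = 0.52 and 0.29). The 31 piRNA pathway genes were split, with 11 higher and 15 lower in HP and 11 higher and 14 lower in LP (10 and 18, and 8 and 18, with total counts). Of 28 insulin, TOR and FOXO genes, 7 and 8 were higher and 10 and 8 lower in HP and LP, but 3 and 4 higher and 18 lower in each with total counts.

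Some genes were seen in 1 line only, chosen after their values were seen, with at most 3 counts over the 9 libraries of the other line. Seen in LP were mthl8 (787 counts against 0 in HP), CG3397 (559 against 0), hui (355 against 0) and the non-coding gene lncRNA:CR44320 (585 against 3). Seen in HP were CG12164 (655 against 3 in LP) and CG42750 (370 against 3). Whether the genes are missing, silent or altered in sequence in the other line was not tested.

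Genes called between diapause and reproductive ovaries, other than eggshell genes, may follow follicles past stage 7 that remained in the dissected ovaries. Scored over the genes called in the other line (75 from HP and 128 from LP), the pooled slope on the eggshell share within groups was 0.0974 towards the reproductive side against 0.2 between the states, upward in HP reproductive and LP diapause ovaries and downward in the other groups. The ratio of 0.487 (exact permutation test over 12 libraries, 1296 permutations, one-sided p = 0.11; ratio 0.402 without the LP diapause group) leaves this open, since older follicles and the state move together. A larger share of somatic tissue in diapause would raise its markers alike and stays open too, since muscle and haemocyte markers were shifted up in both lines (medians 0.31 and 0.26 in HP, 0.57 and 0.36 in LP), while those of fat body (−0.20 in HP, 0.22 in LP), neurons (−0.11, −0.02) and oviduct (−0.02, −0.04) did not pass (adjusted p = 0.43 to 0.96). A difference between the states in cells of stages 1 to 7 stays open as untested.

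Between 2 groups of 3 libraries there are 10 splits, too few for a share under 0.05, and the real split was the 1 with the highest count each time. The real counts and the highest of the other splits were 77 and 0 for HP diapause against reproductive, 6203 and 0 against age control and 5900 and 0 for reproductive against age control. In LP they were 131 and 1, 6502 and 1, and 6108 and 1. For LP against HP they were 2947 and 6 in diapause, 3174 and 0 in reproductive and 3782 and 224 in age-control ovaries. Of 100 drawn combinations of these splits, 1, the real one, gave as many as the 17 genes called in both lines (highest other 0). Since the other splits called at most 0 genes in HP and 1 in LP, the other combinations could share almost none. This count thus adds little to the splits of each line and does not exclude chance. For the diapause-specific genes the regroupings put age controls among the libraries at 12 °C, which widens the spread within groups, so they leave chance open. The real counts and the highest others were 123 and 0 in LP, 17 and 0 in both lines, and 67 and 3553 in HP, where 3 of 100 gave as many and both large counts, 1684 and 3553, came from regroupings with all 3 age controls in the place of diapause, which points to the structure of the samples. Splits cannot test the line difference between diapause and reproductive ovaries, since every split gives at least 0 genes. The count there was 0 by edgeR and 6 by DESeq2. At an unadjusted p under 0.05 by edgeR were 366 of 9037, a share below 0.05.

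LP age-control replicate 2 had counts in 12129 genes, more than any other library, and 471 genes lay over 4 times above every other library, against at most 18 in the others. RNA from testis or another male tissue is a candidate source, since 17 of the 24 testis and male germline genes had their highest level there. Among these were betaTub85D (4.22 CPM against at most 0.714 elsewhere) and Mst98Cb (3.67 against at most 0.165), but the list's summed level of 168 CPM lay between 141 and 175 in the other LP age controls, since twe, which all the ovaries expressed (117 CPM there), made up most of it, and 10 Y-linked genes had 0 counts in all 18 libraries, so this stays open. Sequencing depth is argued against, since 11829 genes had a count after thinning to 14352846 counts, against 11117 in the next library. Of the 471 genes, S-Lap1 among them, 13 were tested, of which 8 were called between LP diapause and age control, 3 in the line difference and 11 between LP and HP age controls, and no biological explanation was tested.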
